A study of Homo sapiens with 18 samples.

How the data were processed

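RNA of HepG2 and Hep3B cells was extracted as total RNA with Trizol, and libraries were made with a TruSeq RNA kit and sequenced on an Illumina HiSeq instrument, per the labels. The authors deposited 2 tables of TPM (transcripts scaled by length to a fixed total per library), estimated with RSEM on hg19 after FastQC, with no tool versions given. The aligner and the annotation release were not given in the sources used here. One table held the 8 libraries of the 24 h experiment and the other the 10 libraries of the 72 h experiment, each with 57773 genes. Of these, 29834 and 29725 were above 0 in at least 1 library. Depth and its precision are unknown, since TPM keeps no read totals, and the strand of the libraries is not stated. The 10 most abundant genes took 11.2 to 17.5% of TPM at 24 h and 12.5 to 17.0% at 72 h.

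Groups were taken from the labels. Gene identifiers were matched to GENCODE release 44 on GRCh37, which held 55538 of them. Genes with a mean TPM of at least 1 over the libraries of a table were tested, 14245 at 24 h and 12680 at 72 h. Values were analysed as log2(TPM + 1), which understates changes of genes with low values, with limma 3.58.1 in R 4.3.3, with all groups of a table in 1 fit and a variance trend on abundance. Residual degrees of freedom were 4 at 24 h and 5 at 72 h, and prior degrees of freedom 3.06 and 4.72. There were 9 comparisons, 1 of them the difference between the lines in their response at 24 h. Genes with a Benjamini-Hochberg adjusted p below 0.05 within a comparison were called, and "rose" and "fell" refer to these and to unshifted log2 changes. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for tables and figures.

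Gene lists covered BET inhibitor markers, WNT signalling, hepatocyte functions, proliferation, stress and inflammatory pathways, metabolism, other cell types and RNA quality. They held 702 members in 39 lists, of which 700 were matched, and the 35 lists with at least 5 tested members were tested with camera of limma at a preset correlation of 0.01, adjusted within each comparison. Camera with a correlation estimated from the data was run beside it. That version rests on the 4 or 5 residual degrees of freedom of the fits, so a call lost with it does not show an unchanged list. The comparisons, lists, tests, the rule for named genes and most alternatives were chosen before the data were examined.

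Named genes were a panel of 10, the 5 largest rises and 5 largest falls, and members of called lists. Rises and falls were ranked among called genes with a mean TPM of at least 5 in the higher group. Values of both libraries of a group had to lie beyond both of the other group. For the difference between the lines this applied to each treated library minus its DMSO mean. Genes with locus, clone, LINC, microRNA, small RNA or antisense names were left out of this ranking. For up to 6 called lists, up to 4 called members with the largest change in the direction of the list were named. Where a list had 5 or fewer called members, those outside this rule were named as well, chosen after their values were seen. The same holds for the genes named in the closing section outside it.

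Alternatives were pseudocounts of 0.1 and 5, no filter and a mean TPM of at least 5, median-ratio scaling, quantile normalization, a replicate block, robust variance moderation, only the libraries compared, and each library left out in turn. Removal of trends with transcript length and GC content (splines with 3 degrees of freedom) and leaving out DMSO replicate 2 and BET inhibitor 4000 nM replicate 2 at 72 h were added after the data were seen. Without a library its group has a single library, assumed to vary like the other groups. Groups of 2 allow no test for outlying libraries and no useful permutation of labels. The fit was tested on simulated data, where it recovered 28 to 38% of genes changed 2-fold in each line at 24 h. It recovered 34 to 46% in the treated groups against DMSO at 72 h, and 14% in the difference between the lines. The simulated noise was independent between genes and of equal spread in all groups, and 200 of the more abundant genes were changed. The real groups differ in spread and in trends with length, so these rates may not hold for them.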

Results

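RNA abundance was measured by sequencing in 18 libraries from 2 human liver cancer cell lines, in 9 groups of 2 libraries. HepG2 is a hepatoblastoma line with an activating deletion in CTNNB1, the gene for beta-catenin, and with wild-type p53. Hep3B is a hepatocellular carcinoma line that lacks p53. In the first experiment both lines received DMSO or a BET inhibitor at 215 nM for 24 h. BET inhibitors keep the bromodomain proteins BRD2, BRD3 and BRD4 off acetylated chromatin, and the labels do not name the compound. In the second experiment HepG2 cells received DMSO, the BET inhibitor at 4000 nM, CHIR98014 at 4000 nM, the BET inhibitor at 4000 nM with CHIR98014 at 72 nM, or the BET inhibitor at 25 nM with CHIR98014 at 4000 nM, all for 72 h. CHIR98014 inhibits GSK3, a kinase of the complex that marks beta-catenin for degradation, so it is used to activate WNT signalling. The series was made to study WNT pathway reactivation and resistance to BET inhibition.

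Values below are TPM, given as mean ± SD of n = 2 libraries, and log2 changes of TPM + 1 with their SE from limma. Where log2 changes are given relative to the median of all genes, every adjusted p, and every "rose", "fell" or "passed", still belongs to the unshifted change, larger or smaller by that median. Depth is unknown, because TPM values keep no read totals. Between 12796 and 14265 genes reached a TPM of 1 in the 24 h libraries, and between 11848 and 13000 in the 72 h libraries. Replicates of 3 groups differed more than the rest: the SD of the log2 difference between the 2 libraries was 0.629 in HepG2 DMSO at 24 h, 0.485 in DMSO at 72 h and 0.521 in BET inhibitor 4000 nM at 72 h, against 0.211 to 0.341 in the other groups. Nothing in the labels says that replicates were separate cultures, so the p-values measure spread between libraries. That spread was pooled for each gene over all groups of a table. It can be too small for groups with wide replicate differences, such as HepG2 DMSO at 24 h. For quieter groups, such as Hep3B DMSO (0.259), it can be too large. The Hep3B controls are described as 0 h libraries in one label field and as vehicle DMSO for 24 h in the design text, and were taken as DMSO.

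The panel of genes named in every comparison lies at these positions of GRCh37, all protein-coding genes with introns included. MYC (ENSG00000136997), a growth-promoting transcription factor, spans 128747680 to 128755197 on chromosome 8. HEXIM1 (ENSG00000186834), which holds the elongation kinase P-TEFb inactive, spans 43225842 to 43229466 on chromosome 17. The WNT feedback genes AXIN2 (ENSG00000168646, 63524681 to 63557766 on chromosome 17), LGR5 (ENSG00000139292, 71833578 to 71980090 on chromosome 12) and NKD1 (ENSG00000140807, 50582307 to 50683160 on chromosome 16) follow. GLUL (ENSG00000135821, 182347233 to 182361341 on chromosome 1) encodes glutamine synthetase. ALB (ENSG00000163631, 74262831 to 74287199) and AFP (ENSG00000081051, 74296855 to 74321891), for albumin and alpha-fetoprotein, are neighbours on chromosome 4. CDKN1A (ENSG00000124762, 36644237 to 36655114 on chromosome 6) encodes the cell cycle inhibitor p21, and MKI67 (ENSG00000148773, 129894923 to 129924687 on chromosome 10) a marker of dividing cells.

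**Figure D1:**
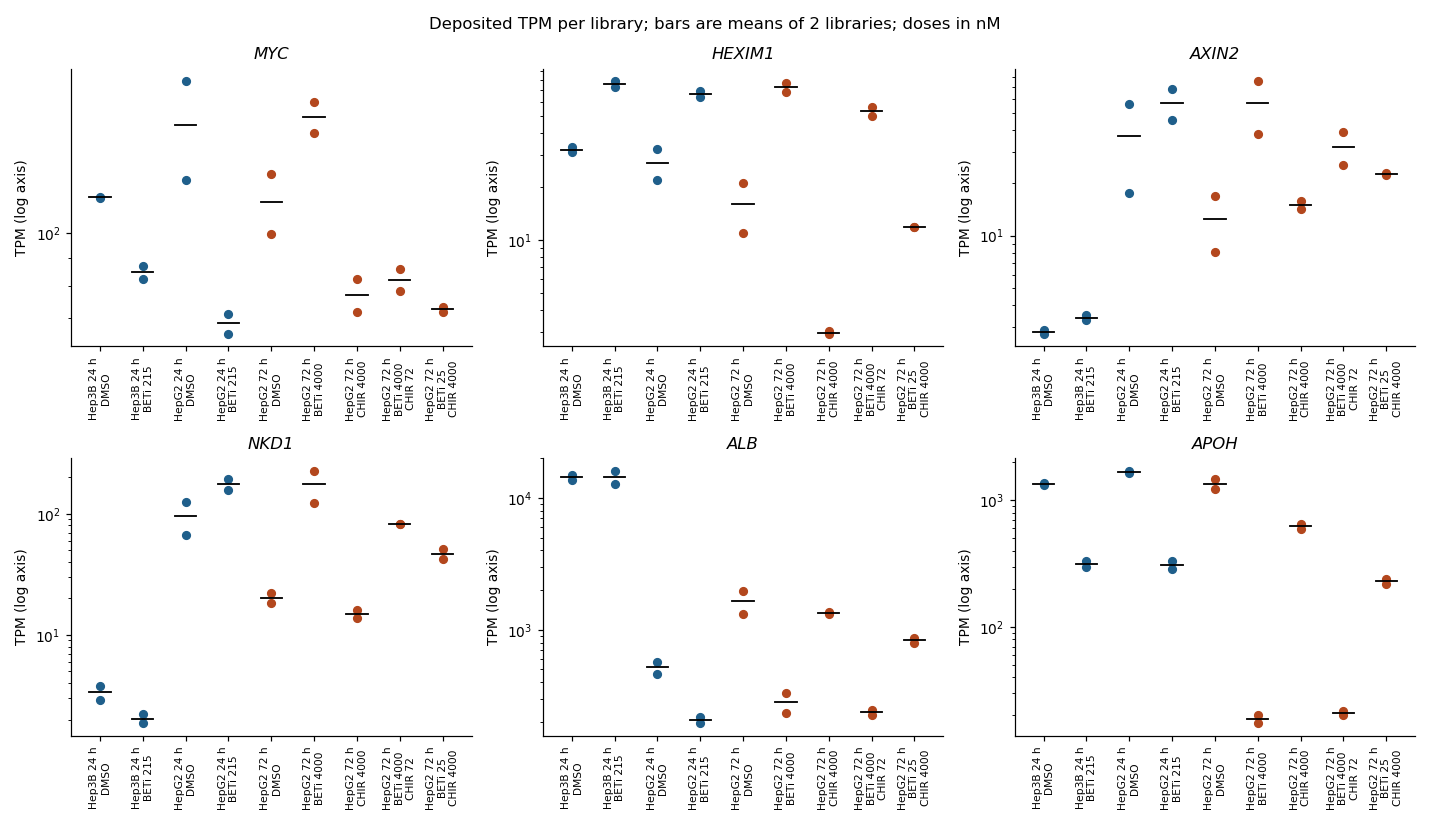
TPM (log axis) of MYC, HEXIM1, AXIN2, NKD1, ALB and APOH in each of the 18 libraries, by group, with bars at the mean of the 2 libraries; the 24 h and 72 h experiments come from separate tables. At 72 h with the BET inhibitor at 4000 nM, NKD1 stood at 175.1 against 20.3 TPM in DMSO and APOH at 18.7 against 1354 TPM.

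After 24 h of the BET inhibitor at 215 nM, HepG2 cells had less RNA of MYC, APOH, ALB and AFP, and more of HEXIM1, DHRS2 and G6PD. MYC fell from 156.3 ± 44.7 to 68.5 ± 4.07 TPM, a log2 change of -1.15 ± 0.19 (adjusted p = 0.0242), and HEXIM1 rose from 27.1 ± 7.62 to 67.1 ± 3.73 TPM (1.3 ± 0.19, adjusted p = 0.0195). APOH, which encodes the plasma glycoprotein beta-2-glycoprotein, fell from 1680 ± 51.0 to 310.1 ± 31.8 TPM (-2.44 ± 0.12, adjusted p = 0.00141). DHRS2, a short-chain dehydrogenase gene, rose from 3048 ± 63.4 to 13990 ± 434 TPM (2.2 ± 0.12, adjusted p = 0.00146). The comparison asks which genes respond to BET inhibition in this line.

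The largest rises in HepG2 at 24 h besides DHRS2 were in HIST2H4A (2.36), G6PD (2.17), the entry enzyme of the pentose phosphate pathway, HIST1H2BD (1.94) and IZUMO4 (1.93). NUPR1, a stress-response gene, fell most (-3.06), followed by NR1H4, the bile acid receptor FXR (-2.79), ODAM (-2.73), INHBE (-2.71), an activin subunit gene, and AREGB (-2.7). Histone genes, ORM1 and ORM2, and AREGB with AREG have near-identical copies or partners, so the split of reads within each family is uncertain. ALB fell from 518.2 ± 74.8 to 207.5 ± 16.7 TPM (-1.31 ± 0.17) and AFP from 2829 ± 559 to 1100 ± 201 TPM (-1.36 ± 0.23). The test was not passed by AXIN2 (0.81 ± 0.48), LGR5 (0.85 ± 0.45), NKD1 (0.92 ± 0.3), GLUL (0.21 ± 0.42), CDKN1A (0 ± 0.16) or MKI67 (0.31 ± 0.42).

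Of 12 BET inhibitor induced markers tested in HepG2 at 24 h, 5 rose and none fell, against 11 and 0 adjusted over the list alone (camera adjusted p = 5.91e-09, and adjusted p = 0.221 with an estimated correlation). The 5 were HIST1H2BD, HIST2H2BE (1.88), HIST1H2AC (1.37), HEXIM1 and HIST1H1C. Integrated stress response genes were lower as a list, with 4 of 20 that fell, TRIB3 (-1.62), PHGDH (-1.1), CEBPB (-0.95) and SHMT2 (-0.89), and 10 lower adjusted over the list alone (camera adjusted p = 3.22e-08, and adjusted p = 0.411 with an estimated correlation). Secreted hepatocyte proteins had 9 of 22 members lower and 0 higher (13 lower and 1 higher adjusted over the list alone) (camera adjusted p = 3.78e-08, and adjusted p = 0.278 with an estimated correlation). APOC3 lay at -2.36, HPX at -1.6 and HP at -1.41. MYC targets and ribosome biogenesis genes were lower as a list, with NOP16 (-0.83), GAR1 (-0.81), RRP12 (-0.74) and CDK4 (-0.69) the 4 lower of 30 and 11 lower adjusted over the list alone (camera adjusted p = 3.1e-07, and adjusted p = 0.221 with an estimated correlation). Acute phase genes were lower as a list too, with 5 of 15 that fell in all genes and 9 adjusted over the list alone: SAA4 (-2.27), ORM2 (-2.15), ORM1 (-1.98), HP and ITIH3 (camera adjusted p = 5.29e-07, and adjusted p = 0.161 with an estimated correlation). Cytosolic ribosomal proteins were lower as a list with no member of 30 passing alone or adjusted over the list alone (median log2 change -0.35, camera adjusted p = 5.29e-07, and adjusted p = 0.609 with an estimated correlation). WNT feedback targets were not called (camera adjusted p = 0.131): NOTUM rose by 0.78 and MYC fell among 17, with 2 higher and 1 lower adjusted over the list alone. The mitochondrially encoded transcripts, a sign of RNA quality, moved with these groups, at a median of 0.61 with 0 of 11 passing (camera adjusted p = 0.000288, and adjusted p = 0.507 with an estimated correlation), and took 12.4 and 8.25% of TPM in DMSO against 14.9 and 14.1% with the inhibitor.

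Of 14245 genes tested, 164 rose and 429 fell in HepG2 at 24 h, 593 in all. The count was 7 without BET inhibitor replicate 1, which ended 29 of the 31 named calls, 57 without replicate 2, which ended 20, 6322 (4693 higher, 1629 lower) without DMSO replicate 1 and 2606 without DMSO replicate 2. Of the named calls, only APOH and DHRS2 passed without each library in turn. It was 1047 (441 higher, 606 lower) after quantile normalization, 1833 (869 higher, 964 lower) with length and GC trends removed and 0 with only these 4 libraries in limma, where 1702 genes had an unadjusted p below 0.05. Median-ratio scaling ended the calls of GAR1 (adjusted p = 0.0722), RRP12 (0.0886) and CDK4 (0.105).

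In Hep3B, 24 h of the BET inhibitor at 215 nM came with much more RNA of PEG10 and HIST1H2BC and much less of LTB, ETV4 and MPZ. Because the median of all tested genes lay 0.11 above DMSO on the log2 scale and scaling by median ratios takes this shift to 0, log2 changes in Hep3B are given relative to that median. LTB, the lymphotoxin beta gene, fell from 147.6 ± 8.26 to 1.19 ± 0.262 TPM (-6.21 ± 0.18, adjusted p = 5.6e-05). ETV4, an ETS transcription factor downstream of MAPK signalling, fell from 52.6 ± 2.09 to 3.25 ± 0.382 TPM (-3.77 ± 0.13, adjusted p = 7.79e-05), and PEG10, an imprinted retrotransposon-derived gene, rose from 327.6 ± 25.5 to 2879 ± 39.1 TPM (3.02 ± 0.2, adjusted p = 0.000519). The comparison asks the same question as in HepG2, in a line without p53.

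Other large falls in Hep3B were in MPZ (-3.93), DEFB1 (-3.75), a defensin gene, and SLC6A19 (-3.7), an amino acid transporter gene. The largest rises were in HIST1H2BC (3.79), HIST2H4A (3.78) and HIST2H2BE (3.37). The pseudogene LSM12P1, listed at 0 in both DMSO libraries, stood at 10.7 and 11.5 TPM with the inhibitor. HEXIM1 rose from 32.3 ± 1.55 to 76.0 ± 3.97 TPM (1.09 ± 0.19, adjusted p = 0.0102) and CDKN1A from 1.48 ± 0.0778 to 3.24 ± 0.276 TPM (0.66 ± 0.16, adjusted p = 0.025). MYC stood at 84.8 ± 3.15 against 115.9 ± 0.184 TPM (-0.56 ± 0.19, adjusted p = 0.182, and 0.0378 with median-ratio scaling), and ALB (-0.11), AFP (-0.63), AXIN2 (0.09), LGR5 (-1.26), NKD1 (-0.63), GLUL (0.16) and MKI67 (0.33) did not pass either, though LGR5 did with median-ratio scaling (adjusted p = 0.0401). With quantile normalization ALB had an unshifted log2 change of -0.50 and passed (adjusted p = 0.0372).

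Integrated stress response genes fell in Hep3B, 13 of 20 and 14 adjusted over the list alone, with TRIB3 (-3.44), CHAC1 (-3.06), STC2 (-2.41) and SLC7A11 (-2.24) the largest (median -1.52, camera adjusted p = 3.98e-12, and adjusted p = 0.315 with an estimated correlation). BET inhibitor induced markers rose, 10 of 12 and 12 adjusted over the list alone (median 2.52, camera adjusted p = 4.26e-12, and adjusted p = 0.187 with an estimated correlation). HIST1H2AC (2.89) and HIST1H2BG (2.77) were among them. NF-kB and chemokine genes fell, 11 of 15, against 12 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.61e-10, and adjusted p = 0.209 with an estimated correlation). ICAM1 lay at -2.63, CXCL10 at -2.52, IL8 at -2.37 and CXCL5 at -1.94. Of 17 immediate early and MAPK feedback genes 5 fell, ETV4, IER3 (-1.92), DUSP5 (-1.62), ETV5 (-1.27) and DUSP4, with 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.94e-05, and adjusted p = 0.538 with an estimated correlation). Of 13 bile acid and transport genes 4 fell, SLC51B (-2.22), SLCO1B3 (-2.05), NR0B2 (-1.78) and FGF19 (-1.68), and 7 adjusted over the list alone (camera adjusted p = 0.000116, and adjusted p = 0.187 with an estimated correlation). Cytosolic ribosomal proteins were lower as a list, with RPS23 (-0.73) the 1 lower of 30 and 0 adjusted over the list alone (camera adjusted p = 1.22e-06, and adjusted p = 0.756 with an estimated correlation). WNT feedback targets were lower, with NOTUM, DKK1 and CCND1 the 3 that fell of 17, in all genes and adjusted over the list alone (median -0.36, camera adjusted p = 0.0441, and adjusted p = 0.756 with an estimated correlation). Leukocyte markers, a list of another cell type, moved with these groups, with CD68, CORO1A and LYZ the 3 that fell of 5, in all genes and adjusted over the list alone (median -1.09, camera adjusted p = 0.00598, and adjusted p = 0.28 with an estimated correlation). A BCL2 family call (camera adjusted p = 0.0205, and adjusted p = 0.314 with an estimated correlation) ended with median-ratio scaling (adjusted p = 0.0754).

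Of 14245 genes tested, 674 rose and 994 fell in Hep3B, 1668 in all. The count was 406 without BET inhibitor replicate 1, 523 without replicate 2, 395 without DMSO replicate 1 and 422 without DMSO replicate 2. Of 30 named calls, 22 passed without each library in turn. Those lost were HEXIM1, CDKN1A, STC2, SLC7A11, IL8, RPS23 and DUSP5 without each of the 4 and ETV5 without DMSO replicate 2 (HEXIM1 at an adjusted p of 0.0913, 0.069, 0.0786 and 0.0912 in that order, ETV5 at 0.0612). It was 4662 (2707 higher, 1955 lower) with only these libraries in the fit, 2719 after quantile normalization, 3226 with length and GC trends removed and 1109 at a mean TPM of at least 5. The RPS23 call ended with median-ratio scaling (adjusted p = 0.139).

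The test of the difference between the lines at 24 h was passed by LTB, ETV4, HP and NOTUM among others, while its 9 list calls were all lost with an estimated correlation. LTB fell in Hep3B but lay below 1 TPM in both HepG2 groups (0.69 ± 0.0849 in DMSO), a difference of 5.42 ± 0.26 between the log2 changes, HepG2 minus Hep3B (adjusted p = 0.000862). ETV4 fell in Hep3B and stood at 179.2 ± 8.01 against 213.9 ± 11.1 TPM in HepG2 (3.4 ± 0.18, adjusted p = 0.00121). HP, the haptoglobin gene, fell in HepG2 from 142.3 ± 20.8 to 52.9 ± 4.78 TPM and stood at 1.15 ± 0.403 TPM in Hep3B DMSO and 9.75 ± 1.34 with the inhibitor (-3.74 ± 0.29, adjusted p = 0.00427). NOTUM, which encodes a secreted WNT inhibitor, stood at 412 ± 10.1 against 239.5 ± 12.1 TPM in HepG2 and at 1.57 ± 0.389 against 8.83 ± 1.3 TPM in Hep3B (2.72 ± 0.23, adjusted p = 0.00569).

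**Figure D2:**
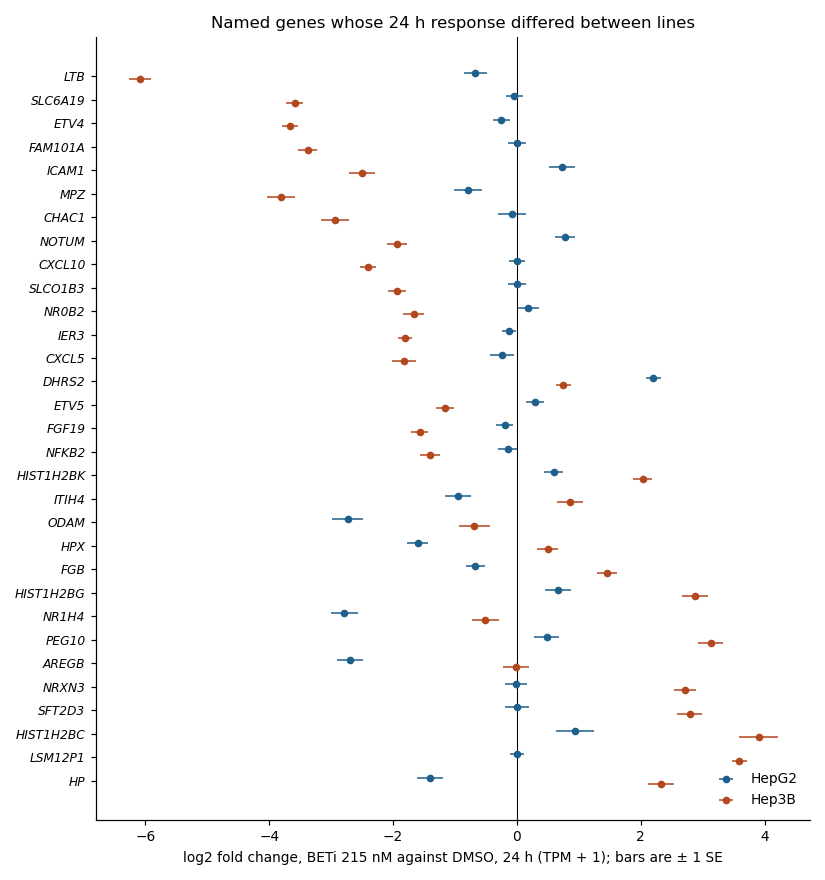
Log2 changes of TPM + 1, BET inhibitor 215 nM against DMSO at 24 h, not shifted by the median gene, with SE bars, for 31 named genes in HepG2 and in Hep3B. LTB lies at -0.67 in HepG2 and -6.09 in Hep3B, and HP at -1.41 and 2.33.

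Among the other differences between lines, SLC6A19 (3.55) and ICAM1 (3.23), an adhesion molecule gene, had higher log2 changes in HepG2, and HIST1H2BC (-2.96) and NRXN3 (-2.74) lower ones. FAM101A, listed at 0 in all 4 HepG2 libraries, fell in Hep3B from 30.5 ± 1.2 to 2.03 ± 0.325 TPM. LSM12P1 and SFT2D3, also listed at 0 in HepG2, were listed at 0 in Hep3B DMSO. No panel gene passed this test, with MYC at -0.7 ± 0.27 (adjusted p = 0.348), HEXIM1 at 0.09 ± 0.28 (0.979), ALB at -1.31 ± 0.24 (0.054) and AXIN2 (0.61), LGR5 (2), NKD1 (1.44), GLUL (-0.07), AFP (-0.85), CDKN1A (-0.77) and MKI67 (-0.13).

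BET inhibitor induced markers had lower changes in HepG2, with HIST1H2BC, HIST1H2BG (-2.22) and HIST1H2BK (-1.45) the 3 lower of 12 and 9 lower adjusted over the list alone (camera adjusted p = 2.99e-07, and adjusted p = 0.345 with an estimated correlation). NF-kB and chemokine genes had higher ones, with ICAM1, CXCL10 (2.41, listed at 0 in HepG2), CXCL5 (1.58) and NFKB2 (1.26) the 4 higher of 15 and 7 adjusted over the list alone (camera adjusted p = 2.99e-07, and adjusted p = 0.36 with an estimated correlation). Higher differences were also found for immediate early and MAPK feedback genes, 3 of 17, ETV4, IER3 (1.67) and ETV5 (1.45), against 11 higher and 3 lower adjusted over the list alone (camera adjusted p = 4.26e-07, and adjusted p = 0.512 with an estimated correlation). Integrated stress response genes had CHAC1 (2.87) as the 1 higher of 20 and 4 adjusted over the list alone (camera adjusted p = 2.47e-05, and adjusted p = 0.6 with an estimated correlation). CHAC1 and CXCL5 lay below 1 TPM in both HepG2 groups, which left little room for a fall there. Acute phase genes had HP, FGB (-2.12) and ITIH4 (-1.81) lower and SERPINA3 higher of 15, against 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00124, and adjusted p = 0.345 with an estimated correlation). WNT feedback targets had NOTUM as the 1 higher of 17, in all genes and adjusted over the list alone (median 0.46, camera adjusted p = 0.00143, and adjusted p = 0.704 with an estimated correlation).

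The difference passed for 232 of 14245 genes, 137 with a higher and 95 with a lower change in HepG2. Its direction depended on single libraries. The median log2 difference over all genes was 0.146 without HepG2 DMSO replicate 1 and -0.251 without replicate 2, against -0.051 with all libraries. The count was 5 without either HepG2 BET inhibitor library, 1999 and 2658 without HepG2 DMSO replicate 1 and 2, 45 and 47 without Hep3B BET inhibitor replicate 1 and 2, and 35 and 61 without Hep3B DMSO replicate 1 and 2. Of 21 named calls, LTB, SLC6A19, ETV4 and LSM12P1 passed without each library in turn. It was 434 after quantile normalization, 100 at a mean TPM of at least 5, 83 and 436 with a pseudocount of 0.1 and 5, and 526 with length and GC trends removed. ITIH4 lost its call with median-ratio scaling (adjusted p = 0.0608).

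Across the 14245 genes, log2 changes in the 2 lines had a Pearson correlation of 0.535 and a Spearman correlation of 0.568, genes not being independent replicates. Calls overlapped in 87 genes higher in both lines, against 7.8 for independent calls, and 221 lower in both, against 29.9, while 8 went in opposite directions. HEXIM1, HIST2H4A and HIST2H2BE were among those higher in both lines, and TRIB3 and SLC51B among those lower in both. With length and GC trends removed, 1029 rather than 308 genes were shared in direction.

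After 72 h of the BET inhibitor at 4000 nM, HepG2 cells had far less RNA of ORM1, APOH and AFP, and more of NKD1, AXIN2 and G6PD. The median of all tested genes lay 0.44 above DMSO on the log2 scale, and median-ratio scaling takes this shift to near 0, so log2 changes at 72 h are given relative to the median of their comparison. ORM1, for the plasma protein orosomucoid, fell from 1202 ± 154 to 6.83 ± 2.02 TPM (-7.72 ± 0.25, adjusted p = 2.94e-07), APOH from 1354 ± 177 to 18.7 ± 1.87 TPM (-6.54 ± 0.15, adjusted p = 4.26e-08) and AFP from 5432 ± 1690 to 647.4 ± 2.41 TPM (-3.47 ± 0.28, adjusted p = 5.67e-05). NKD1 rose from 20.3 ± 2.47 to 175.1 ± 73.3 TPM (2.56 ± 0.26, adjusted p = 3.38e-05) and AXIN2 from 12.4 ± 6.19 to 56.9 ± 26.7 TPM (1.68 ± 0.37, adjusted p = 0.00179). The comparison asks what a high dose over 3 days changes in this line.

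WNT feedback targets rose with the BET inhibitor at 72 h, 14 of 17 with 0 lower, and 15 adjusted over the list alone, led by NOTUM (2.66), NKD1, TNFRSF19 (2.46) and DKK1 (2.24), 3 of them inhibitors of the pathway (median 0.98, camera adjusted p = 0.00054, and adjusted p = 0.633 with an estimated correlation). In the same fit 4695 of all 12680 genes rose. With median-ratio scaling 11 of the 17 targets were higher and 0 lower. LGR5 rose from 4.82 ± 2.16 to 14.3 ± 3.91 TPM (0.99 ± 0.35 relative to the median, and adjusted p = 0.00851 for the unshifted change), and GLUL (-0.29), CDKN1A (-0.01) and MKI67 (-0.29) did not pass. With length and GC trends removed GLUL passed at an unshifted log2 change of -0.469 (adjusted p = 0.0348). MYC stood at 161.8 ± 14.9 against 113.5 ± 19.9 TPM, passed at its unshifted log2 change of 0.52 ± 0.16 (adjusted p = 0.0262) and lay at 0.08 relative to the median. With median-ratio scaling it did not pass (adjusted p = 0.938). HEXIM1 rose from 16.0 ± 7.17 to 72.9 ± 5.83 TPM (1.75 ± 0.26, adjusted p = 0.000209). The BET inhibitor induced markers rose with it, 10 of 11 in all genes and adjusted over the list alone (median 1.53, camera adjusted p = 0.000998, and adjusted p = 0.374 with an estimated correlation).

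**Figure D3:**
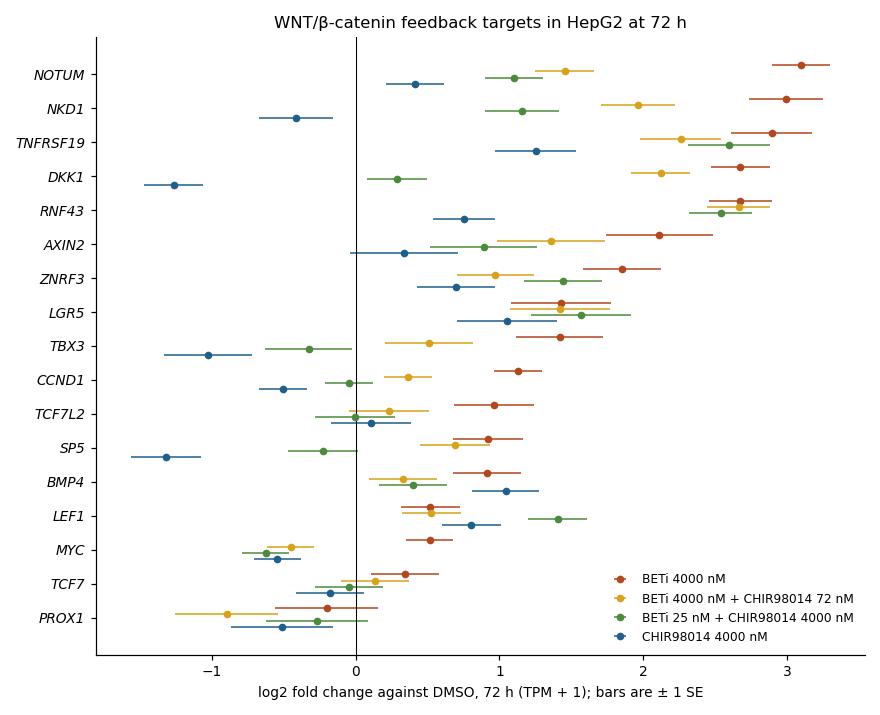
Log2 changes of TPM + 1 against DMSO at 72 h, not shifted by the median gene, with SE bars, for 17 WNT feedback targets in the 4 treated HepG2 groups. NOTUM lies at 3.1 and DKK1 at 2.68 with the BET inhibitor at 4000 nM, and DKK1 at -1.26 with CHIR98014 at 4000 nM.

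The largest other rises at 72 h were in FOS (3.49), an immediate early gene, NEAT1 (3.39), a nuclear long noncoding RNA, G6PD (3.07) and HHLA3 (2.89). FAM3C2, a pseudogene listed at 0 in both DMSO libraries, stood at 5.86 and 16.8 TPM. The sulfotransferase gene SULT2A1 (-6.79), ORM2 (-7.33) and the steroid dehydrogenase gene HSD17B2 (-6.23) fell most besides ORM1 and APOH. ALB fell from 1643 ± 464 to 283.1 ± 68.4 TPM (-2.96 ± 0.21). Bile acid and transport genes fell, 7 of 10 and 9 adjusted over the list alone, with NR1H4 (-4.71), the transporter genes SLC51B (-4.68), SLC51A (-3.39) and ABCC3 (-2.62) (median -2.58, camera adjusted p = 5.87e-09, and adjusted p = 0.0431 with an estimated correlation). This was the only one of 16 calls of the comparison that held with an estimated correlation, and it was lost with length and GC trends removed as well (adjusted p = 0.115). Secreted hepatocyte proteins had 13 lower and 4 higher of 21, against 13 and 5 adjusted over the list alone, with APOM (-4.31), APOC3 (-3.83) and SERPINC1 (-3.64) falling and the fibrinogen genes FGA and FGG, HP and APOA1 rising (camera adjusted p = 6.15e-08, and adjusted p = 0.0711 with an estimated correlation). Periportal hepatocyte genes had 7 lower of 12 and CPS1 the 1 higher, in all genes and adjusted over the list alone, with HAL (-3.61), HPD (-3.34), ASS1 (-2.52) and TAT (-2.51) (camera adjusted p = 6.45e-06, and adjusted p = 0.403 with an estimated correlation). Hepatocyte transcription factors had 6 lower of 16 and 0 higher, in all genes and adjusted over the list alone (camera adjusted p = 0.000116, and adjusted p = 0.467 with an estimated correlation). HNF4A (-2.92), HNF1A (-2.88) and NR0B2 (-2.56) were among them. Cytosolic ribosomal proteins fell, 19 of 30 in all genes and adjusted over the list alone, with RPS19 at -1.77 and RPL30 at -1.39 (median -1, camera adjusted p = 3.36e-11, and adjusted p = 0.467 with an estimated correlation). Leukocyte markers, a list of another cell type, were lower as a list, with CD68 and LYZ the 2 that fell of 5, in all genes and adjusted over the list alone (camera adjusted p = 0.0222, and adjusted p = 0.329 with an estimated correlation). This call ended with length and GC trends removed (camera adjusted p = 0.0829). All 11 mitochondrially encoded transcripts rose, in all genes and adjusted over the list alone (median 0.46, camera adjusted p = 0.0108, and adjusted p = 0.725 with an estimated correlation; 0.0938 with median-ratio scaling and the preset correlation).

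Of 12680 genes tested, 4695 rose and 1561 fell with the BET inhibitor at 72 h, and 2801 rose and 2976 fell with median-ratio scaling and 3228 and 2607 after quantile normalization. The 6256 calls became 4032 without BET inhibitor replicate 2 and 4053 without DMSO replicate 2, which ended the calls of MYC (adjusted p = 0.129 and 0.135) and LGR5 (0.055 and 0.0662), 4606 (2663 higher, 1943 lower) without both, 7539 (5956 higher) without BET inhibitor replicate 1, 7185 (5704 higher) without DMSO replicate 1 and 2834 with only the libraries compared. With 2 libraries in a group, no test can tell which of them stands apart. DMSO replicate 2 and BET inhibitor replicate 2 were the lowest and highest of the 72 h libraries in genes at a TPM of at least 1 (11848 and 13000). They were also the lowest and highest in the mitochondrially encoded share of TPM (8.16 and 19.7%). In all, 36 of 38 named calls passed without each library in turn.

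In HepG2 the effects of 215 nM for 24 h and 4000 nM for 72 h, each against its own DMSO libraries, had a Pearson correlation of 0.733 and a Spearman correlation of 0.706 across 12257 genes. Calls overlapped in 152 genes higher in both, against 59.6 for independent calls, and 310 lower in both, against 45.5, with 8 in opposite directions. APOH, ORM1, NR1H4, ALB and AFP were lower in both and G6PD and HEXIM1 higher in both, while MYC fell at 24 h and lay at 0.08 relative to the median at 72 h. Dose and time both differ, so the difference is assigned to neither, and the 462 genes shared in direction were 307 at a mean TPM of at least 5 and 1397 with length and GC trends removed.

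CHIR98014 at 4000 nM for 72 h came with more RNA of UGT1A1, IL8 and MCM3 in HepG2, less of HEXIM1, UBALD2 and HSD17B2, and WNT feedback targets that went both ways. IL8, a neutrophil chemokine gene, rose from 10.4 ± 2.25 to 157.7 ± 24.7 TPM (3.64 ± 0.3 relative to a median of all genes 0.17 above DMSO, adjusted p = 6.65e-05). MCM3, a subunit of the replicative helicase, rose from 23.0 ± 5.37 to 106.7 ± 12.9 TPM (2.01 ± 0.19, adjusted p = 0.00013). HEXIM1 fell from 16.0 ± 7.17 to 3.0 ± 0.0636 TPM (-2.18 ± 0.26, adjusted p = 0.000688). CDKN1A rose from 40.1 ± 10.9 to 100.8 ± 3.29 TPM (1.17 ± 0.19, adjusted p = 0.0012). AXIN2 stood at 15.0 ± 1.2 against 12.4 ± 6.19 TPM (0.17 ± 0.37, adjusted p = 0.533) and NKD1 at 15.0 ± 1.63 against 20.3 ± 2.47 TPM (-0.58 ± 0.26, adjusted p = 0.257). The comparison asks what GSK3 inhibition changes without the BET inhibitor.

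WNT feedback targets were not called with CHIR98014 (median -0.06, camera adjusted p = 0.594). Of 17 members LGR5 (0.89), LEF1, RNF43, TNFRSF19 and BMP4 rose, DKK1, SP5, TBX3, MYC (-0.71) and CCND1 fell. In that list 6 rose and 5 fell adjusted over the list alone. UGT1A1 (6.44), UGT1A6 (5.26) and UGT1A8 (3.97), glucuronosyltransferase genes that share their 3′ exons so that the split of reads is uncertain, rose most with NT5E (3.78), the CD73 gene. FAM3C2, which stood at 18.0 and 15.8 TPM, was listed at 0 in DMSO. UBALD2 (-5.24), HSD17B2 (-4.28), C10orf10 (-4.26), TCP11L2 (-4.19) and the metallothionein gene MT2A (-4.01) fell most. GLUL (-0.78), ALB (-0.43), AFP (-0.81) and MKI67 (0.09) did not pass. With median-ratio scaling NKD1 (adjusted p = 0.0269), GLUL (0.00849) and ALB (0.0409) did.

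DNA replication genes rose with CHIR98014, 17 of 24 in all genes and adjusted over the list alone, with MCM2 and MCM4 at 1.59 and MCM10 at 1.23 (median 0.88, camera adjusted p = 1.17e-06, and adjusted p = 0.705 with an estimated correlation). MYC targets and ribosome biogenesis genes rose, 18 of 30 and 24 adjusted over the list alone (camera adjusted p = 1.92e-05, and adjusted p = 0.705 with an estimated correlation). BOP1 lay at 1.83 and TFRC at 1.57, UTP20 at 1.07 and WDR43 at 1.02. NF-kB and chemokine genes rose, 9 of 12 and 10 adjusted over the list alone (median 1.37, camera adjusted p = 7.91e-05, and adjusted p = 0.705 with an estimated correlation). BIRC3 lay at 2.54, NFKBIA at 2 and CXCL2 at 1.97 beside IL8. Immediate early and MAPK feedback genes were lower as a list, with 7 of 18 that fell in all genes and adjusted over the list alone (camera adjusted p = 0.00262, and adjusted p = 0.792 with an estimated correlation). EGR1 (-1.83), DUSP6 (-1.55), IER2 (-1.52) and ETV4 (-1.46) were among them. Bile acid and transport genes were lower as a list, with SLC51B (-3.72), SLC51A (-2.66), BAAT (-1.26), ABCB4 (-0.91) and CYP27A1 the 5 lower of 10 and 5 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00366, and adjusted p = 0.588 with an estimated correlation). Cytosolic ribosomal proteins were lower, with RPS8 (-0.82) and RPL37 (-0.69) the 2 lower of 30 and 0 adjusted over the list alone (camera adjusted p = 0.00126, and adjusted p = 0.872 with an estimated correlation). Both genes lost their calls with median-ratio scaling (0.0738 and 0.0857). Of 11 mitochondrially encoded transcripts 8 rose, and 11 adjusted over the list alone (median 0.57, camera adjusted p = 0.00262, and adjusted p = 0.872 with an estimated correlation).

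Of 12680 genes tested, 2239 rose and 1260 fell with CHIR98014, 3499 in all, and 2043 rose and 2305 fell with median-ratio scaling and 2372 and 2026 after quantile normalization. The count was 1442 without CHIR98014 replicate 1 and 1145 without replicate 2, and 24 of 36 named calls passed without each library in turn. The 12 others, MYC, LGR5, UTP20, RPS8, RPL37, EGR1, DUSP6, ABCB4, MCM10, TFRC, WDR43 and BAAT, were lost without CHIR98014 replicate 2, and 8 of them also without replicate 1, 3 without DMSO replicate 1 and 5 without DMSO replicate 2.

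With CHIR98014 at 72 nM added to the BET inhibitor at 4000 nM, HepG2 cells at 72 h again had less RNA of APOH, AFP and ALB than in DMSO, and more of NKD1 and HEXIM1. APOH fell from 1354 ± 177 to 20.99 ± 1.15 TPM (-6.14 ± 0.15 relative to a median of all genes 0.2 above DMSO, adjusted p = 5.52e-08). AFP fell from 5432 ± 1690 to 522.9 ± 233 TPM (-3.62 ± 0.28, adjusted p = 2.9e-05). NKD1 rose from 20.3 ± 2.47 to 81.8 ± 0.0849 TPM (1.76 ± 0.26, adjusted p = 0.000417). HEXIM1 rose to 53.3 ± 4.2 TPM (1.54 ± 0.26, adjusted p = 0.000829). The comparison asks what the 2 compounds together change against DMSO. No group received CHIR98014 at 72 nM alone, so the effect of the BET inhibitor in its presence was not measured.

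ALB (-2.97) fell and CDKN1A (0.77), AXIN2 (1.15) and LGR5 (1.22) rose with this combination, while MYC (-0.65, adjusted p = 0.0582, and 0.00424 with median-ratio scaling), GLUL (-0.24) and MKI67 (-0.95, and adjusted p = 0.00933 with median-ratio scaling) did not pass. The histone genes HIST1H2AE (3.52), HIST1H2BD (3.49) and HIST2H2AA4 (3.49) rose most with VGF (3.45), a neuropeptide precursor gene. FAM3C2 was listed at 0 in DMSO and at 13.2 and 27.2 TPM here. ORM1 (-7.12), ORM2 (-7.03), HSD17B2 (-6.04) and PDIA2 (-5.51) fell most besides APOH.

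With the combination WNT feedback targets were higher as a list, with 8 of 17 that rose and 0 lower, against 10 higher and 2 lower adjusted over the list alone (median 0.49, camera adjusted p = 0.00849, and adjusted p = 0.637 with an estimated correlation). BET inhibitor induced markers rose, 10 of 11 in all genes and adjusted over the list alone (camera adjusted p = 1.11e-06, and adjusted p = 0.128 with an estimated correlation). HIST1H1C lay at 2.91 and HIST2H2BE at 2.83. Bile acid and transport genes fell, 8 of 10 in all genes and adjusted over the list alone (camera adjusted p = 1.11e-06, and adjusted p = 0.0794 with an estimated correlation). NR1H4 lay at -4.24, SLC51B at -3.9 and ABCC3 at -3.35. Periportal hepatocyte genes had 9 lower of 12 and CPS1 the 1 higher, in all genes and adjusted over the list alone (camera adjusted p = 4.05e-06, and adjusted p = 0.4 with an estimated correlation). HAL (-3.37), ASS1 (-3.08) and PCK1 (-2.76) were among the lower ones. Secreted hepatocyte proteins had 13 lower and 4 higher of 21, in all genes and adjusted over the list alone. APOM (-4.73), TTR (-3.74) and APOC3 (-3.29) fell, and APOA1, FGG, HP and TF were the 4 higher (camera adjusted p = 4.46e-06, and adjusted p = 0.128 with an estimated correlation). Hepatocyte transcription factors had 8 lower of 16, and 9 adjusted over the list alone (camera adjusted p = 8.43e-06, and adjusted p = 0.4 with an estimated correlation). HNF4A lay at -2.91 and HNF1A at -2.71. Cytosolic ribosomal proteins had 7 lower of 30 and RPS2 the 1 higher, against 6 and 0 adjusted over the list alone (camera adjusted p = 1.85e-05, and adjusted p = 0.637 with an estimated correlation). RPS19 lay at -1.15. Mitotic genes were lower as a list, with 9 of 24 that fell and 11 adjusted over the list alone (median -0.88, camera adjusted p = 1.85e-05, and adjusted p = 0.637 with an estimated correlation). Of 11 mitochondrially encoded transcripts 8 rose, and 11 adjusted over the list alone (median 0.66, camera adjusted p = 0.0019, and adjusted p = 0.637 with an estimated correlation).

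Of 12680 genes tested, 2611 rose and 1672 fell with the combination, 4283 in all, and 2371 rose and 2592 fell with median-ratio scaling, which ended the calls of RPS14 (adjusted p = 0.0805) and RPL30 (0.0634). The count was 2531 without combination replicate 1 and 2516 without replicate 2, and 32 of 38 named calls passed without each library in turn. AXIN2, LGR5, RPS19, RPS14, RPL37 and RPL30 were lost without combination replicate 2 and without DMSO replicate 2 (AXIN2 at an adjusted p of 0.142 and 0.135), and RPS14 also without combination replicate 1 (0.0602).

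With the BET inhibitor at 25 nM added to CHIR98014 at 4000 nM, HepG2 cells at 72 h had more RNA of UGT1A1, ICAM1 and SLC2A3 than in DMSO, and less of HSD17B2, PDIA2 and UBALD2. ICAM1 rose from 37.9 ± 7.61 to 358.6 ± 10 TPM (2.9 ± 0.19 relative to a median of all genes 0.32 above DMSO, adjusted p = 1.3e-05). SLC2A3, a glucose transporter gene, rose from 75.1 ± 3.9 to 413.2 ± 7.12 TPM (2.12 ± 0.21, adjusted p = 6.82e-05). HSD17B2 fell from 71.1 ± 5.32 to 2.33 ± 0.445 TPM (-4.76 ± 0.21, adjusted p = 9.5e-06). NKD1 rose to 46.5 ± 6.12 TPM (0.83 ± 0.26, adjusted p = 0.00764), while HEXIM1 stood at 11.8 ± 0.0778 TPM (-0.66 ± 0.26 relative to the median, and adjusted p = 0.325 for the unshifted change, against 0.0151 with median-ratio scaling). The comparison asks what the 2 compounds together change against DMSO. No group received the BET inhibitor at 25 nM alone, so the effect of CHIR98014 in its presence was not measured.

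UGT1A1 (5.89), UGT1A6 (4.74), UGT1A8 (4.35) and ERP27 (3.76) rose most. FAM3C2, at 31.4 and 13.7 TPM, was listed at 0 in DMSO. PDIA2 (-5.3), UBALD2 (-5.23) and TCP11L2 (-4.49) fell with HSD17B2. HBB, a globin gene, passed narrowly at -5.54 ± 1.85 (adjusted p = 0.0498), with 47.5 and 77.9 TPM in DMSO. LGR5 (1.24) and CDKN1A (1.06) rose, MYC (-0.95) and ALB (-1.28) fell, and AXIN2 (0.57), GLUL (-0.61), AFP (-1.08) and MKI67 (-0.07) did not pass. With median-ratio scaling GLUL (adjusted p = 0.0203) and AFP (0.0454) did.

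WNT feedback targets were not called (median 0.07, camera adjusted p = 0.299), with 7 higher and MYC the 1 lower of 17, in all genes and adjusted over the list alone. Cytosolic ribosomal proteins fell, 16 of 30 and 18 adjusted over the list alone (camera adjusted p = 1.15e-09, and adjusted p = 0.474 with an estimated correlation). RPL13 lay at -1.48 and RPS14 at -1.38. Bile acid and transport genes were lower as a list, with SLC51B (-4.23), SLC51A (-3.1), NR1H4 (-2.26), ABCC3 (-1.71) and BAAT the 5 lower of 10, in all genes and adjusted over the list alone (camera adjusted p = 0.0001, and adjusted p = 0.181 with an estimated correlation). DNA replication genes rose, 18 of 24 and 21 adjusted over the list alone (camera adjusted p = 0.0001, and adjusted p = 0.474 with an estimated correlation). MCM3 lay at 1.9, MCM4 at 1.3 and CCNE1 at 1.06. NF-kB and chemokine genes rose, 8 of 12 and 9 adjusted over the list alone (camera adjusted p = 0.000304, and adjusted p = 0.338 with an estimated correlation). IL8 lay at 3.33, BIRC3 at 2.29 and NFKBIA at 1.8 beside ICAM1. Periportal hepatocyte genes had 6 lower of 12 and CPS1 the 1 higher, in all genes and adjusted over the list alone (camera adjusted p = 0.000304, and adjusted p = 0.474 with an estimated correlation). HAL lay at -2.42, TAT at -2.21 and ASS1 at -1.95. Hypoxia and glycolysis genes had 13 higher of 19 and ANKRD37 and SLC2A1 the 2 lower, in all genes and adjusted over the list alone (camera adjusted p = 0.00405, and adjusted p = 0.605 with an estimated correlation). ALDOC lay at 2.02 and ALDOA at 1.47. All 11 mitochondrially encoded transcripts rose, in all genes and adjusted over the list alone (median 0.62, camera adjusted p = 0.00237, and adjusted p = 0.665 with an estimated correlation).

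Of 12680 genes tested, 3441 rose and 1317 fell with this combination, 4758 in all, and 2729 rose and 2188 fell after quantile normalization, and 2264 and 2513 with median-ratio scaling, which ended the HBB call (adjusted p = 0.0533). The count was 2169 without combination replicate 1, 2094 without replicate 2 and 2889 without DMSO replicate 2, with 29 of 39 named calls passed without each library in turn. The losses were 8 without combination replicate 1 (MYC, LGR5, HBB, RPL13, RPS14, RPS8, RPL37 and PCK1), 6 without replicate 2 (MYC, NKD1, ALB, HBB, RPL13 and PCK1), HBB alone without DMSO replicate 1 (adjusted p = 0.0915). LGR5, HBB, RPL13, RPS14 and RPS8 were lost without DMSO replicate 2.

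Set against the BET inhibitor at 4000 nM alone, the addition of CHIR98014 at 72 nM came with less RNA of MYC, UBALD2 and CDK1 and more of PAEP. PAEP, the glycodelin gene, rose from 5.14 ± 0.297 to 39.5 ± 8.97 TPM (2.93 ± 0.2 relative to a median of all genes 0.23 below the BET inhibitor alone, adjusted p = 0.00179). MYC fell from 161.8 ± 14.9 to 82.2 ± 5.37 TPM (-0.74 ± 0.16, adjusted p = 0.0253). UBALD2 fell from 19.9 ± 3.18 to 2.24 ± 0.156 TPM (-2.45 ± 0.27, adjusted p = 0.00708). The comparison asks what low-dose GSK3 inhibition adds to BET inhibition.

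C19orf80 (3.06), CEMP1 (2.78), SULT2A1 (2.17) and the iron-binding protein gene LCN2 (1.99) rose most besides PAEP. ABTB1 (-2.34), the kinase gene PIM1 (-2.32), the transporter gene SLC38A3 (-2.14) and KLHL24 (-2.09) fell most besides UBALD2. The other panel genes did not pass, with NKD1 at -0.8 (adjusted p = 0.0798), AXIN2 at -0.53, LGR5 at 0.22, HEXIM1 at -0.22, GLUL at 0.05, ALB at -0.02, AFP at -0.16, CDKN1A at 0.77 (adjusted p = 0.0377 with median-ratio scaling) and MKI67 at -0.67. Mitotic genes were lower, with CDK1 (-0.96) and CDC20 (-0.67) the 2 lower of 24 and 22 lower adjusted over the list alone (camera adjusted p = 6.05e-08, and adjusted p = 0.481 with an estimated correlation). DNA replication genes were lower, with MCM7 (-0.91) and E2F1 (-0.64) the 2 lower of 24 and 14 adjusted over the list alone (camera adjusted p = 6.28e-06, and adjusted p = 0.399 with an estimated correlation). BET inhibitor induced markers were higher, with HIST1H2BC (1.45) and HIST1H2BK (1.32) the 2 higher of 11 and 5 adjusted over the list alone (camera adjusted p = 2.74e-06, and adjusted p = 0.386 with an estimated correlation). NRF2 targets were higher, with the heme oxygenase gene HMOX1 (1.42) the 1 higher of 16 and 3 adjusted over the list alone (camera adjusted p = 1.25e-05, and adjusted p = 0.386 with an estimated correlation). WNT feedback targets were lower, with MYC and NOTUM the 2 lower of 17 and 6 adjusted over the list alone (median -0.47, camera adjusted p = 0.00109, and adjusted p = 0.481 with an estimated correlation). Cytosolic ribosomal proteins were higher relative to other genes, with 0 of 30 passing in limma over all genes or adjusted over the list alone (median 0.42, camera adjusted p = 3.18e-09, and adjusted p = 0.481 with an estimated correlation). MYC targets and ribosome biogenesis genes were also higher, with 0 of 30 passing and 5 higher adjusted over the list alone (median 0.37, camera adjusted p = 1.72e-07, and adjusted p = 0.386 with an estimated correlation).

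Of 12680 genes tested, 56 rose and 165 fell, 221 in all, and 153 rose and 177 fell after quantile normalization, and 137 and 179 with median-ratio scaling, which ended the calls of CDC20 (adjusted p = 0.0711) and E2F1 (0.149). The count was 1 without combination replicate 1, 4 without replicate 2, 2577 without BET inhibitor replicate 1, 42 without BET inhibitor replicate 2. It was 72 with a replicate block (19 higher, 53 lower), 739 with length and GC trends removed and 119 with no filter on low values. With only these 4 libraries in limma it was 0, where 1461 genes had an unadjusted p below 0.05. Of 18 named calls, those lost were 17 without combination replicate 1, 15 without replicate 2 and 10 without BET inhibitor replicate 2. PAEP alone passed without each library in turn.

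Set against CHIR98014 at 4000 nM alone, the addition of the BET inhibitor at 25 nM came with more RNA of DHRS2, HEXIM1 and NKD1, and less of ORM1 and SAA4. DHRS2 rose from 567.5 ± 92.0 to 3464 ± 201 TPM (2.48 ± 0.21 relative to a median of all genes 0.13 above CHIR98014 alone, adjusted p = 0.00114). HEXIM1 rose from 2.99 ± 0.0636 to 11.8 ± 0.0778 TPM (1.55 ± 0.26, adjusted p = 0.00874). NKD1 rose from 15.0 ± 1.63 to 46.5 ± 6.12 TPM (1.44 ± 0.26, adjusted p = 0.0106). ORM1 fell from 423.8 ± 2.52 to 66.2 ± 2.98 TPM (-2.79 ± 0.25, adjusted p = 0.00169). The comparison asks what low-dose BET inhibition adds to GSK3 inhibition.

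NEAT1 (2.2), FOS (1.97), ADI1 (1.93), an enzyme gene of methionine salvage, and ZG16B (1.89) rose most besides DHRS2. SAA4 (-3.19), PDIA2 (-3.07), ORM2 (-2.76) and FAM69C (-2.59) fell most besides ORM1. The other panel genes did not pass, with ALB at -0.83 (adjusted p = 0.0906, and 0.0166 with median-ratio scaling), MYC at -0.22, AXIN2 at 0.42, LGR5 at 0.38, GLUL at 0.2, AFP at -0.25, CDKN1A at -0.08 and MKI67 at -0.14. WNT feedback targets were higher, with RNF43 (1.65), NKD1, DKK1 (1.42), TNFRSF19 (1.21) and SP5 the 5 higher of 17 and 9 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.00176, and adjusted p = 0.644 with an estimated correlation). BET inhibitor induced markers were higher, with HEXIM1, HIST1H2BC (1.26), HIST2H2BE (1.23) and HIST1H1C (0.62) the 4 higher of 11 and 8 adjusted over the list alone (camera adjusted p = 0.00011, and adjusted p = 0.644 with an estimated correlation). Periportal hepatocyte genes were lower, with ARG1 (-1.93), ASS1 (-1.76) and HPD (-1.66) the 3 lower of 12, in all genes and adjusted over the list alone (camera adjusted p = 0.000149, and adjusted p = 0.644 with an estimated correlation). Hypoxia and glycolysis genes were higher as a list, with 6 of 19 that rose and 9 adjusted over the list alone (camera adjusted p = 0.00176, and adjusted p = 0.644 with an estimated correlation). SLC2A3 lay at 1.71, ADM at 1.5, ALDOA at 1.26 and ALDOC at 0.99. MYC targets and ribosome biogenesis genes were lower, with PES1 (-0.72) the 1 lower of 30 and 0 adjusted over the list alone (camera adjusted p = 0.000149, and adjusted p = 0.644 with an estimated correlation). Cytosolic ribosomal proteins were lower with 0 of 30 passing in limma over all genes or adjusted over the list alone (median -0.35, camera adjusted p = 5.01e-06, and adjusted p = 0.644 with an estimated correlation).

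Of 12680 genes tested, 449 rose and 275 fell, 724 in all, and 527 rose and 615 fell (1142) with median-ratio scaling, which ended the calls of HIST1H1C (adjusted p = 0.193) and PES1 (0.0786). The count was 72 without combination replicate 1, 14 without replicate 2, 28 without CHIR98014 replicate 1 and 35 without CHIR98014 replicate 2. It was 342 (196 higher, 146 lower) with a replicate block and 1157 (568 higher, 589 lower) after quantile normalization. With length and GC trends removed it was 1901, and with only these 4 libraries 4377. Of 26 named calls, those lost were 12 and 20 without combination replicate 1 and 2 and 17 and 14 without CHIR98014 replicate 1 and 2. ADI1, DHRS2, FAM69C, ORM1, ORM2 and SAA4 passed without each library in turn.

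Doses of the 2 compounds were not crossed, so no interaction of BET and GSK3 inhibition was tested at 72 h. Across the 9 comparisons, 7 of 35 tested lists had no call, with the smallest adjusted p at 0.142 for BET proteins and P-TEFb, 0.179 for WNT ligands and receptors, 0.0903 for the beta-catenin destruction complex, 0.104 for pericentral hepatocyte genes, 0.128 for fatty acid synthesis, 0.0695 for interferon response and 0.696 for mitochondrial fatty acid oxidation. At the preset correlation, BET inhibitor induced markers were called in 8 of the 9 comparisons. The list of BET inhibitor repressed markers, which holds MYC, was called in only 2 (smallest camera adjusted p = 0.000288).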

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

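Of the tests weighed in this part, the share of higher genes without 2 libraries, the gain outside abundant genes, the median-ratio value of the WNT targets and the within-group difference of HBB were chosen after the result was seen.

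A test of the difference between HepG2 and Hep3B in their response to the BET inhibitor at 24 h singled out 232 genes, and those named are given here as HepG2 minus Hep3B. Genes that fell in Hep3B and changed less in HepG2 were ETV4 (3.4), MPZ (3.03), NR0B2 (1.85), IER3 (1.67), ETV5 (1.45) and NFKB2 (1.26). LTB (5.42), SLC6A19 (3.55), FAM101A (3.38), CHAC1 (2.87), CXCL10 (2.41), SLCO1B3 (1.94), CXCL5 (1.58) and FGF19 (1.37) fell in Hep3B but lay below 1 TPM in both HepG2 groups, which left little or no room for a fall there. ICAM1 (3.23) and NOTUM (2.72) fell in Hep3B and had positive log2 changes in HepG2, and DHRS2 (1.45) rose more in HepG2. Genes that rose in Hep3B and changed less in HepG2 were HIST1H2BC (-2.96), NRXN3 (-2.74), PEG10 (-2.66), HIST1H2BG (-2.22) and HIST1H2BK (-1.45), with LSM12P1 (-3.59) and SFT2D3 (-2.79) listed at 0 outside treated Hep3B cells. HP (-3.74), FGB (-2.12), HPX (-2.1) and ITIH4 (-1.81) had negative log2 changes in HepG2 and positive ones in Hep3B. NR1H4 (-2.28) and ODAM (-2.04) fell in HepG2 and changed less in Hep3B, and AREGB (-2.69) fell in HepG2 and lay below 1 TPM in both Hep3B groups.

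The same test between the lines called 9 lists. These were BET inhibitor induced markers (camera adjusted p = 2.99e-07), NF-kB and chemokine genes (2.99e-07), immediate early and MAPK feedback genes (4.26e-07), integrated stress response genes (2.47e-05), acute phase genes (0.00124), WNT feedback targets (0.00143), secreted hepatocyte proteins (0.00823), BCL2 family genes (0.0218) and leukocyte genes (0.0343). Each call was lost with an estimated correlation, at adjusted p = 0.345, 0.36, 0.512, 0.6, 0.345, 0.704, 0.6, 0.36 and 0.39 in that order.

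More genes were higher than lower with the BET inhibitor at 4000 nM at 72 h, 75% of those called in the main fit. The share was 57.8% without DMSO replicate 2 and BET inhibitor replicate 2, a pair picked after the data were seen, and 64.9 to 79.4% without each library of both groups in turn, so single libraries were neither shown nor excluded as the cause. The log2 change correlated with transcript length at 0.22 (Spearman, 12377 genes) and at -0.03 without that pair, so the trend was not weighed apart from these libraries, and the share was 54.8% with length and GC trends removed, which leaves it open. Genes outside the 100 most abundant of DMSO gained 1.14 times in share of TPM, which could not tell scaling by abundant transcripts from a response, and median-ratio scaling (48.5%) and quantile normalization (55.3%) draw the libraries to a common centre by design. A broad biological rise cannot be told from these causes without a measure of RNA per cell.

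Higher WNT feedback targets with the BET inhibitor at 4000 nM at 72 h had an unshifted median log2 change of 1.42 over 17 genes, 0.98 relative to all genes. The unshifted median was 0.91 with length and GC trends removed (median absolute deviation 1.19, 13 higher and 1 lower), 0.9 without DMSO replicate 2 and BET inhibitor replicate 2 (0.83, 10 higher and 1 lower) and 0.95 with median-ratio scaling (1.16, 11 higher and 0 lower). Each lay above the 0.3 set as the bound for a technical cause. This argues against length and GC trends and against those 2 libraries as the whole cause, though the spread between members is wide. The median-ratio value largely restates the 0.98 relative to all genes, so it is no separate test of scaling. The call of the list was lost with an estimated correlation (adjusted p = 0.633), so a response to the inhibitor stays open as an untested explanation.

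Beta-globin RNA was uneven across the 72 h libraries, with HBB at 47.5 and 77.9 TPM in DMSO, 193.3 and 0.62 with the BET inhibitor at 4000 nM, 24.2 and 0.37 with CHIR98014 and below 1 in the other 4. The alpha-globin genes HBA1 and HBA2 stood at 48.3 and 99.99 TPM in the BET inhibitor library with most HBB and at 1.5 and 0.71 in the other, with 31.1 and 16 in the first DMSO library and 44.5 and 33.7 in the second. With CHIR98014 HBA1 stood at 24.5 and 11.7 TPM and HBA2 at 10.45 and 3.2, and HBA1 ranged from 2.09 to 5.04 in HepG2 at 24 h, where HBB was 0, so alpha-globin RNA did not follow HBB in every library. Of 10 other erythroid genes 1 reached 0.1 TPM only in the library with most HBB; the bound written beforehand was met, but a single library and genes near the floor exclude nothing, so red cell RNA stays open, as does carry-over from other libraries, which was not tested. The 2 BET inhibitor libraries differ by 6.91 in log2(TPM + 1) of HBB, which restates the pattern and decides nothing on a treatment response.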

How the results depend on the processing

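Length and GC trend removal and the joint exclusion of 2 libraries were chosen after the data were seen. Counts below are called genes, and where they moved the cause was not tested. Without each library in turn, with a lone sample assumed to vary like the other groups, counts ran from 7 to 6322 for HepG2 at 24 h (593 with all), 395 to 523 for Hep3B (1668), 5 to 2658 for the line difference (232), 4032 to 7539 for the BET inhibitor at 72 h (6256), 1145 to 4241 for CHIR98014 (3499), 2516 to 4922 for the BET inhibitor with CHIR98014 at 72 nM (4283), 2094 to 5705 for CHIR98014 with the BET inhibitor at 25 nM (4758), 1 to 2577 for added CHIR98014 (221) and 14 to 72 for added BET inhibitor (724). These fits have fewer residual degrees of freedom. The difference between the 2 libraries of the affected group also no longer enters the pooled spread, so counts can rise as well as fall.

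Quantile normalization gave 1047 for HepG2 at 24 h, 2719 for Hep3B, 434 for the line difference and 1157 for added BET inhibitor, and median-ratio scaling 1142 for the last. With only the libraries compared there were 0 in limma for HepG2 at 24 h (1702 at an unadjusted p below 0.05), 4662 for Hep3B, 2834 for the BET inhibitor at 72 h, 0 for added CHIR98014 (1461 unadjusted) and 4377 for added BET inhibitor. A mean TPM of at least 5 gave 1109 for Hep3B, 100 for the line difference and 307 for genes shared by 24 h and 72 h, pseudocounts of 0.1 and 5 gave 83 and 436 for the line difference, and no filter gave 119 for added CHIR98014. Length and GC trend removal gave 1833 for HepG2 at 24 h, 3226 for Hep3B, 526 for the line difference, 739 and 1901 for added CHIR98014 and BET inhibitor, 1029 genes shared by the lines and 1397 shared by 24 h and 72 h.

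Replicate numbers are shared by the groups, and the labels do not say whether they mark a shared day or batch. Between DMSO and the BET inhibitor, replicate deviations correlated at 0.563 in HepG2 and 0.196 in Hep3B at 24 h. At 72 h the DMSO and BET inhibitor 4000 nM groups correlated at -0.592. Pairing was thus neither shown nor excluded. A replicate block gave 72 for added CHIR98014 and 342 for added BET inhibitor and kept the other 7 counts within 1.5 times. Robust variance moderation kept all 9 counts within 1.5 times.

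Of 335 named values, 306 kept their side of the threshold with median-ratio scaling, 319 with quantile normalization and 310 with length and GC trends removed. With no filter on low values 289 kept it and 46 calls were lost, and with a replicate block 311 kept it and 23 calls were lost. With only the libraries compared, not run for the line difference, 242 kept it, 57 calls were lost and 5 were gained. ALB in Hep3B, at an unshifted 0.0036 in the main fit, passed at -0.499 with quantile normalization (adjusted p = 0.0372), and GLUL with the BET inhibitor at 72 h, at an unshifted 0.144, passed at -0.469 with trends removed (adjusted p = 0.0348). Of 315 list results, 194 were the same and 121 weaker with an estimated correlation. The only call kept was that of bile acid and transport genes with the BET inhibitor at 4000 nM at 72 h. The other results counted as the same were never calls. Depth is unknown, so its limits on low genes could not be set.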

Other observations

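The FOXO test in this part was set before its result was seen, and no test in it was chosen afterwards.

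Lists of sterol and sugar metabolism were called with the BET inhibitor at 72 h at the preset correlation alone, in a comparison where 4695 of 12680 genes rose. Cholesterol synthesis genes had 16 of 23 higher and 0 lower with the BET inhibitor at 4000 nM, in all genes and adjusted over the list alone (median 0.3 relative to all genes, camera adjusted p = 0.0147, and adjusted p = 0.725 with an estimated correlation). Hypoxia and glycolysis genes had 12 higher of 19 and EGLN3 the 1 lower, against 12 and 2 adjusted over the list alone (camera adjusted p = 0.0187, and adjusted p = 0.725 with an estimated correlation), a call that ended with median-ratio scaling (0.0734). When CHIR98014 at 72 nM was added to the inhibitor, YAP targets were lower, with CRIM1, CTGF and CYR61 the 3 that fell of 13 and 6 adjusted over the list alone (median -0.66, camera adjusted p = 0.00044, and adjusted p = 0.481 with an estimated correlation). These lists were picked for mention after their values were seen.

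UBALD2, TCP11L2 and C10orf10 fell with CHIR98014 at 4000 nM, and KLHL24 and ABTB1 fell when 72 nM was added to the BET inhibitor, which raised the hypothesis of lower FOXO-dependent transcription. A list of FOXO targets tested for CHIR98014 against DMSO had an unshifted median log2 change of -0.64 over 13 of 14 members, with PNRC1 (-0.97), TRIB1 (-1.36) and IRS2 (-0.81) the 3 lower and 0 higher, and a camera p of 0.00461. With an estimated correlation the p was 0.285, above the threshold. By the rule written beforehand, this outcome went against the hypothesis. A p above the threshold excludes nothing, however, so the test could not tell. The list was computed in 6 comparisons at 72 h. When 72 nM was added to the BET inhibitor its unshifted median was -0.95, with 0 higher and PNRC1 the 1 lower (camera p 0.00257, and p = 0.259 with an estimated correlation). With the BET inhibitor alone 9 members were higher and 1 lower (camera p 0.0948, and p = 0.512 with an estimated correlation). Against DMSO, the BET inhibitor with 72 nM had 3 higher and 3 lower (unshifted median 0.12, camera p 0.809, and p = 0.923 with an estimated correlation), and CHIR98014 with the BET inhibitor at 25 nM had 2 higher and 3 lower (-0.44, 0.0347 and 0.413). Against CHIR98014 alone, the added BET inhibitor had 2 higher and 0 lower (0.4, 0.211 and 0.62).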
